A study of Mus musculus with 6 samples.

How the data were processed

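Poly(A) RNA from 6 livers of FVB mice aged 84 days, 3 Ing5 +/+ and 3 heterozygous for the MommeD48 allele, was extracted with Trizol and made into Illumina TruSeq RNA libraries, per the labels' protocols. Reads were processed with TopHat2 2.0.11, HTSeq 0.6.1 and DESeq against mm9, per the submitters' processing notes, which name these tools without their role, and the counting strand and the annotation release were not given in the sources used here. The deposited values are whole-number counts per gene, not normalised, for 37991 Ensembl gene IDs in each of the 6 libraries. No row for unassigned reads was found, so every row entered the library totals. Gene symbols were matched by Ensembl ID in the reference name table for 32919 IDs, and 5072 IDs had none and took 0.554% to 0.823% of the counts. The reference annotation was of another build than the files, so it was used only for names and for which genes neighbour each other, and no coordinates are given.

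Genotype and replicate number were taken from the labels. Total counts per library were 20830886, 22041117 and 19840541 for WT replicates 1 to 3 and 21402396, 21272147 and 20032822 for Het replicates 1 to 3. Alb took 5.85% to 7.70% of the counts, mitochondrial genes 10.8% to 13.4% and the 20 most abundant genes 25.5% to 28.3%, so transcripts of low abundance are measured at a correspondingly lower depth. Libraries were compared pairwise by chi-square over genes with a total count of at least 10 to look for libraries deposited more than once, and none was found.

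Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr by genotype, which left 12631 genes, normalised with TMM and fitted with the robust quasi-likelihood model with genotype as the sole factor. TMM factors ranged from 0.977 to 1.02, the biological coefficient of variation was 0.134 and the median SE of the log2 fold change was 0.125. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and SE and 95% intervals were derived from the F statistic of each gene. The Ing5 level was also tested by an exact two-sided permutation test, for which 0.1 is the smallest possible p. Lists of genes, 42 in all, covered liver pathways, subunits of ING5 complexes, silencing factors, genes near Ing5, imprinted genes, stress and sample quality, and the cell types of the liver and of adjacent tissues. The 35 lists with at least 5 tested genes were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and the others were given as summed CPM. List scores are the mean over members of log2 CPM minus the mean of the 6 libraries.

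Samples, lists, tests and most alternatives were fixed before the data were examined. The genes named were Ing5, up to 12 genes per direction with the largest fold change past the threshold or, where fewer than 5 passed, the 5 with the smallest unadjusted p in that direction at a mean log2 CPM of at least 0, called members of each list or otherwise its 2 most abundant members, the 3 most abundant genes and the sex chromosome genes. The 2 members with the smallest p in each list that passed, Trp53, and genes named for passing under an alternative or adjusted over a list alone were added after their values were seen. So were Saa1, Saa2, Orm2, Lcn2, Sqle and Cyp4a14, named for differences within a genotype, and Ugt1a2, Col6a3, Bok and Sag, named as neighbours of Ing5 with an unadjusted p under 0.05. Lists that did not pass are given partly without examples.

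The alternatives were DESeq2 size factors, no low-count filter, a filter at a CPM above 1 in 3 libraries, library sizes without the 20 most abundant genes, no robust estimation, the replicate number as a block, a threshold of 0.1, DESeq2 1.42.0, limma-voom, each library left out in turn, and for lists camera with an estimated correlation and fry. The newer quasi-likelihood fit of edgeR, the acute-phase score as a covariate, the p53 target list without Cdkn1a, and the estimated correlation in the fits with a library left out, the covariate or the replicate block were added after the data were seen. A covariate for sex was planned but not run, because all 6 livers were of 1 sex by their transcripts. The steps were tested on counts simulated for the 12631 genes with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold: edgeR recovered 26, 49 and 65 of them with 15 false calls among 12431 unchanged genes, DESeq2 gave 27 false calls and limma-voom 10. With no gene changed, edgeR called 1 gene, DESeq2 6 and limma-voom 0. A simulated list of 20 genes shifted by 0.4 (log2) had an adjusted p of 1.02e-19 with camera and the preset correlation, 0.0177 with the estimated one and 0.00156 with fry, and 0 of 35 unchanged lists passed. Each gene was simulated independently of the others. The simulations therefore could not show false calls from genes that vary together between livers.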

Results

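RNA sequencing counts were analysed from 6 livers of FVB mice aged 84 days, 3 with the genotype Ing5 +/+ (WT) and 3 heterozygous for the MommeD48 allele of Ing5 (Het). Ing5 encodes a PHD-finger protein of the inhibitor of growth family, a subunit of histone acetyltransferase complexes. MommeD alleles come from a mouse screen for genes that modify the silencing of a transgene. The comparison asked how a single copy of the mutant allele affects liver transcripts. Total gene counts per library ranged from 19840541 to 22041117, and 16323 to 16597 genes had at least 1 count. A count of 0, for which up to 3 counts were allowed, corresponded to at most 0.136 to 0.151 CPM (counts scaled to library size), and this floor covers counting error only. CPM values below are normalised group means ± SD (n = 3), and fold changes are log2 of Het over WT with their standard error (SE). The labels number the livers within a genotype without saying that each came from a separate mouse, so p-values measure only the spread between these samples, which may be technical. No library was a copy of another, since the chi-square per degree of freedom between libraries was 10.2 to 79.9.

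All 6 livers carried male transcripts. Ddx3y, a Y-linked helicase gene, had 1644 to 1956 counts per library, Eif2s3y 1306 to 1456, Uty 510 to 563 and Kdm5d 306 to 508. Xist, the transcript of the inactive X chromosome, had 1 to 6 counts and its antisense gene Tsix 12 to 50. The most abundant transcripts were Alb, the gene of serum albumin, with 63845 ± 8578 CPM in WT and 67608 ± 9897 CPM in Het livers, and the mitochondrial genes mt-Co1 and mt-Co3. The hepatocyte identity genes summed to 113787 ± 7105 CPM in WT and 120176 ± 6838 CPM in Het livers. Markers of tissues that can be carried over at dissection were scarce: pancreatic acinar markers summed to 47.4 ± 8.68 and 52.98 ± 8.81 CPM, gallbladder and gut markers to 0.466 ± 0.200 and 0.604 ± 0.210 CPM, adipocyte markers to 26.0 ± 4.23 and 25.1 ± 4.93 CPM, and muscle and mesothelium markers to 4.01 ± 1.15 and 4.48 ± 1.08 CPM in WT and Het livers, respectively.

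Ing5 (ENSMUSG00000026283, chromosome 1) was transcribed at a similar level in both genotypes. Its counts were 182, 228 and 191 in the WT libraries and 193, 217 and 180 in the Het libraries. These corresponded to 9.65 ± 0.807 CPM in WT and 9.33 ± 0.607 CPM in Het livers. The log2 fold change was -0.05 (SE 0.11, 95% interval -0.30 to 0.20), a fold of 0.968 with an interval of 0.814 to 1.15. This interval excludes the fold of 0.5 that would follow if 1 of the 2 alleles gave no RNA. The difference did not pass the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.9998), and the exact two-sided permutation p was 0.8, where 0.1 is the smallest p that 3 against 3 livers allow. The labels do not say what kind of mutation the allele is. Leaving out WT replicate 2 turned the sign of the log2 fold change, to 0.00771.

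The 5 genes with the smallest p-values among those with higher values in Het livers were Slco2a1, Slc16a1, Abca8a, Gm16551 and Dnaic1, and among those with lower values Gnat1, Cdkn1a, Cpeb1, Sbk1 and Cyp21a2-ps. Slco2a1, a prostaglandin transporter, had 44.7 ± 3.65 CPM in WT and 63.4 ± 3.99 CPM in Het livers (log2 fold change 0.50, SE 0.09). Slc16a1, a monocarboxylate transporter, had 47.1 ± 1.10 and 62.1 ± 1.69 CPM (0.40, SE 0.07), and Abca8a, an ATP-binding cassette transporter, 159 ± 9.53 and 228 ± 16.6 CPM (0.52, SE 0.10). The predicted gene Gm16551 had 6.18 ± 0.240 and 10.2 ± 1.10 CPM (0.72, SE 0.12), and Dnaic1, an axonemal dynein intermediate chain gene, 0.982 ± 0.0759 and 3.29 ± 1.25 CPM (1.74, SE 0.32). Lower values in Het livers were found for Gnat1, the rod transducin alpha subunit, with 9.04 ± 1.80 and 3.32 ± 0.817 CPM (-1.45, SE 0.21), and for Cdkn1a, a cyclin-dependent kinase inhibitor, with 1.87 ± 0.418 and 0.603 ± 0.127 CPM (-1.63, SE 0.29). The same direction held for Cpeb1, a regulator of cytoplasmic polyadenylation, with 7.66 ± 0.536 and 4.47 ± 0.713 CPM (-0.78, SE 0.15), the kinase gene Sbk1 with 21.7 ± 1.08 and 15.1 ± 1.67 CPM (-0.53, SE 0.10), and Cyp21a2-ps with 2.55 ± 0.854 and 0.792 ± 0.272 CPM (-1.69, SE 0.33). Cyp21a2-ps is a pseudogene, so its counts are uncertain because reads can be shared with its functional copy. For each of these 10 genes the 3 Het values lay on 1 side of the 3 WT values, but none passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.529 to 0.599). With DESeq2, Gnat1, Abca8a, Dnaic1, Slco2a1, Cyp21a2-ps and Gm16551 passed (Benjamini-Hochberg adjusted p = 1.11e-05 to 0.0396). In a simulation with no gene changed, DESeq2 called 6 genes and edgeR 1.

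**Figure D1:**
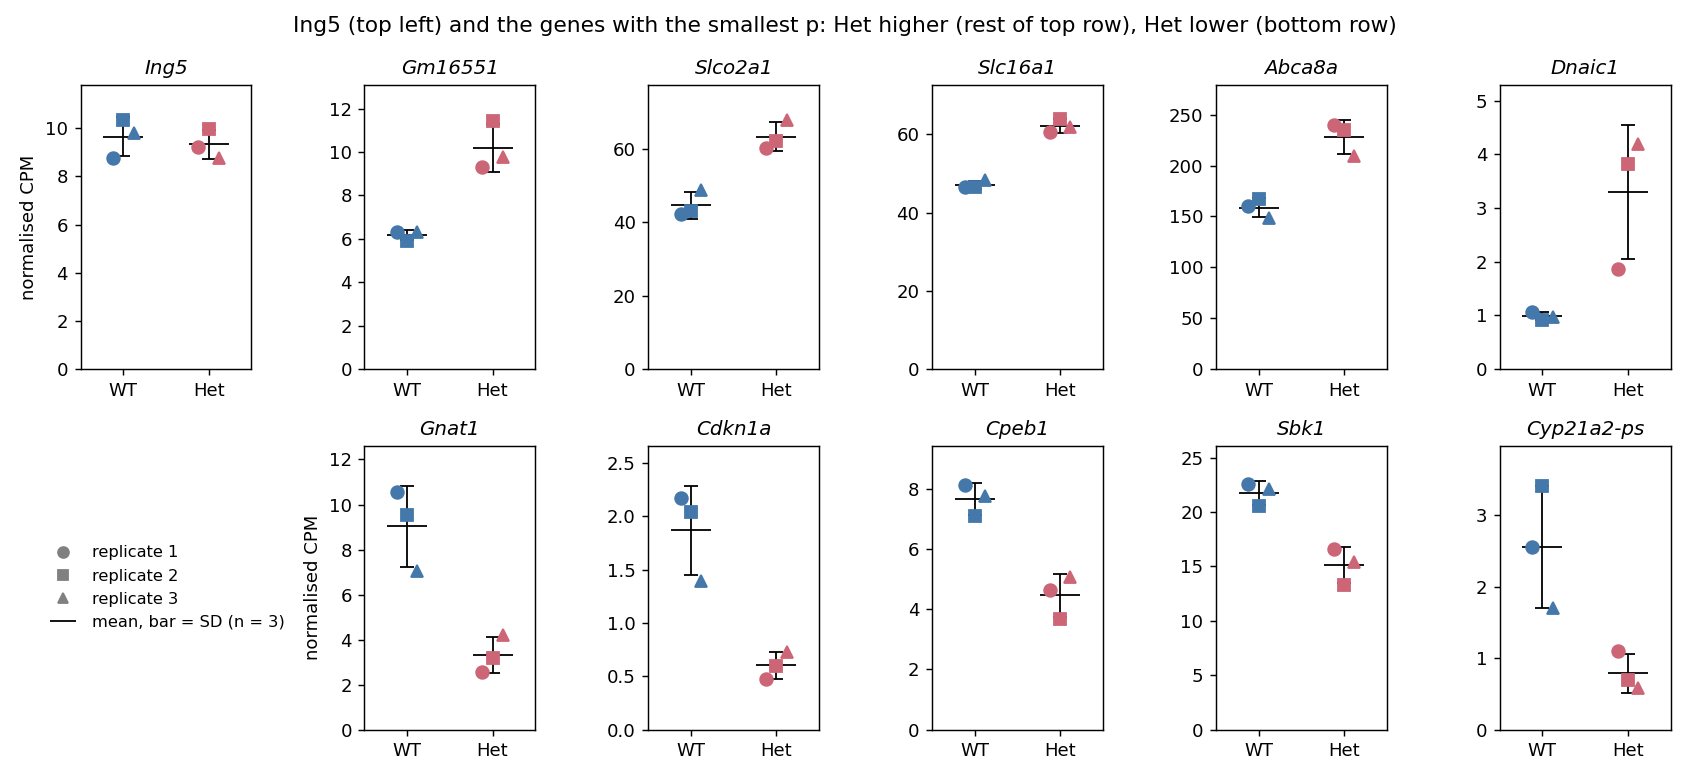
Normalised CPM (vertical axes, from 0) of Ing5 and of the 10 genes with the smallest p-values in the WT and Het livers, with a point per library and the mean ± SD of 3 livers. Ing5 overlaps between the genotypes at 8.77 to 10.4 CPM, while Gnat1 lies at 7.05 to 10.5 CPM in WT and 2.58 to 4.197 CPM in Het livers.

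Over the 12631 genes tested, 0 passed an adjusted p of 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.529. Of these genes, 547 had an unadjusted p under 0.05, 268 with higher and 279 with lower values in Het livers. With limma-voom 0 genes passed. With DESeq2 14 genes passed, 10 higher and 4 lower in Het livers, and the strongest by adjusted p were Gnat1 (adjusted p = 1.11e-05) and Ugt2b38, a glucuronosyltransferase gene (adjusted p = 1.11e-05). Het and WT values were separated for 1136 genes (8.99%), where chance gives 10% for 3 against 3. The 95% interval of the fold change lay within a 2-fold change for 11373 genes (90.0%) and within a 1.5-fold change for 8979 genes (71.1%). On simulated counts for the same 12631 genes and the same comparison, the edgeR test recovered 38.8% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 98.5% of those changed 4-fold. Genes were simulated independently, so these shares need not hold where genes vary together between livers. The simulation also changed 67, 67 and 66 genes at once. Where fewer genes change, the adjustment asks for a smaller p, so the shares can be lower. In the livers Gnat1, at a log2 fold change of -1.45, had an adjusted p of 0.529 (edgeR, Benjamini-Hochberg). The 0 genes passed thus do not exclude changes of 2-fold or more in single genes. The count of 0 rested on individual livers: it was 17 without WT replicate 3 (Gnat1 and Slco2a1 among them) and 10 without Het replicate 1 (Dnaic1 among them), and these sets shared 0 genes.

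Among 35 lists of genes tested with camera, 11 passed an adjusted p of 0.05 with a preset correlation of 0.01 between genes, 3 with higher and 8 with lower values in Het livers. The lower lists were p53 targets, female-biased liver genes, fatty acid synthesis, acute phase, cell cycle, interferon response, gluconeogenesis and fasting, and erythroid markers. The higher lists were male-biased liver genes, cytosolic ribosomal proteins and imprinted genes. None of the 11 passed when the correlation was estimated from the libraries, where the smallest adjusted p of any list was 0.207 (camera, Benjamini-Hochberg). The same was true of fry, which tests whether the genes of a list move 1 way on balance, with a smallest adjusted p of 0.191 (Benjamini-Hochberg). In each of these 11 lists 0 members passed the edgeR test adjusted over all genes.

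Targets of p53, the transcription factor that responds to DNA damage, had lower values in Het livers in 19 of 22 tested members. The median log2 fold change of the list was -0.20, and its mean score was 0.20, 0.20 and 0.06 in the WT libraries against -0.13, -0.19 and -0.13 in the Het libraries. The most abundant members were Ei24, with 168 ± 8.03 CPM in WT and 153 ± 14.7 CPM in Het livers, and Perp, with 77.2 ± 2.65 and 71.5 ± 13.1 CPM. Cdkn1a passed when adjusted over the list alone (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00509), and it was the only member to do so. Eda2r, a death receptor gene chosen after the values were seen, had 1.15 ± 0.718 and 0.348 ± 0.0176 CPM, and Trp53 itself 16.9 ± 2.40 and 18.0 ± 0.418 CPM. Eda2r had a log2 fold change of -2.04 without WT replicate 3 and -1.13 without WT replicate 1. The list's camera test gave a Benjamini-Hochberg adjusted p of 2.41e-09 with the preset correlation and adjusted p = 0.207 with an estimated correlation.

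Genes with sex-biased expression in mouse liver had median fold changes in opposite directions for female-biased and male-biased genes, but not every liver followed. The female-biased scores were 0.33, 0.08 and 0.55 in the WT and 0.04, -0.41 and -0.58 in the Het libraries. The male-biased scores overlapped, at 0.055, -0.17 and -0.25 in the WT and 0.0007, 0.078 and 0.29 in the Het libraries (exact permutation p = 0.2). Of 15 female-biased genes 12 had lower values in Het livers, with a median log2 fold change of -0.55 (camera, Benjamini-Hochberg adjusted p = 1.11e-07; adjusted p = 0.472 with an estimated correlation). The most abundant of them, Cyp2b9, had 86.2, 102 and 99.6 CPM in the WT libraries and 97.8, 20.8 and 20.9 CPM in the Het libraries, and Acot3, an acyl-CoA thioesterase gene, 37.6 ± 13.2 and 25.6 ± 15.1 CPM. The log2 fold change of Acot3 ran from -1.01 without Het replicate 1 to -0.16 without Het replicate 3. Adjusted over the list alone, 2 passed, Slc22a29 (log2 fold change -0.92, SE 0.22) and the hydroxyacid oxidase gene Hao2 (-1.56, SE 0.44). Of 19 male-biased genes 15 had higher values in Het livers, with a median of 0.16 (camera, Benjamini-Hochberg adjusted p = 3.94e-05; adjusted p = 0.472 with an estimated correlation). Adjusted over the list alone, 3 passed: Cyp7b1, an oxysterol hydroxylase gene, with 327 ± 6.18 and 482 ± 65.7 CPM, the steroid dehydrogenase gene Hsd3b5, with 235 ± 21.0 and 326 ± 9.26 CPM, and Ugt2b38, with 11.6 ± 2.34 and 29.2 ± 9.20 CPM. These 3 genes also passed over all genes with DESeq2 (Benjamini-Hochberg adjusted p = 1.11e-05 to 0.00831), but not with edgeR. DESeq2 used the same counts, and it called 6 genes in a simulation with no gene changed, where edgeR called 1. The most abundant male-biased genes, Serpina3k and Slco1a1, had 9007 ± 1609 and 1445 ± 85.6 CPM in WT and 9735 ± 480 and 1616 ± 116 CPM in Het livers. Cyp2b, Ugt2b, Hsd3b and Serpina3 genes have near-identical copies, so their values are uncertain where reads were split between copies. Cyp2b9 had a log2 fold change of -1.04 with all 6 libraries (unadjusted p = 0.225) and of -0.69 without Het replicate 2 or Het replicate 3. It passed the edgeR test with Benjamini-Hochberg adjustment over all genes only without Het replicate 1 (-2.20, adjusted p = 0.00012).

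In the fatty acid synthesis list and the gluconeogenesis and fasting list most members had lower values in Het livers. Of 21 fatty acid synthesis genes 15 had lower values, with a median log2 fold change of -0.30 (camera, Benjamini-Hochberg adjusted p = 2.87e-07; adjusted p = 0.472 with an estimated correlation). Scd1, a stearoyl-CoA desaturase gene, had 2261 ± 696 CPM in WT and 1048 ± 846 CPM in Het livers, while the desaturase gene Fads1 had 560 ± 51.1 and 571 ± 66.5 CPM. Single livers moved the log2 fold change of Scd1, from -1.98 without Het replicate 1 to -0.71 without Het replicate 2. The smallest p-values in this list belonged to the elongase gene Elovl6, with 51.2 ± 2.69 and 36.8 ± 6.72 CPM, and the malic enzyme gene Me1, with 268 ± 42.0 and 198 ± 15.3 CPM. Of 20 gluconeogenesis and fasting genes 17 had lower values, with a median of -0.18 (camera, Benjamini-Hochberg adjusted p = 0.00265; adjusted p = 0.472 with an estimated correlation). Pck1, which encodes a rate-limiting gluconeogenic enzyme, had 2031 ± 281 and 1446 ± 551 CPM, Tat, a tyrosine aminotransferase gene, 808 ± 274 and 729 ± 300 CPM, and Fbp1, a fructose bisphosphatase gene, 746 ± 112 and 600 ± 57.9 CPM. The log2 fold change of Pck1 ran from -0.80 without Het replicate 3 to -0.24 without Het replicate 2. Nnmt, a nicotinamide methyltransferase gene, had 26.7, 19.6 and 5.25 CPM in the WT libraries and 3.44, 3.22 and 2.64 CPM in the Het libraries, and it passed the edgeR test with Benjamini-Hochberg adjustment only without WT replicate 3 (adjusted p = 0.000524). No member of either list passed adjusted over the list alone (0 and 0 genes), while 5 and 2 had an unadjusted p under 0.05. The gluconeogenesis list did not pass without Het replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.0706).

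Acute-phase genes, which the liver induces in inflammation, spread more widely within genotypes than between them. Of 26 members 24 had lower values in Het livers, with a median log2 fold change of -0.56 (camera, Benjamini-Hochberg adjusted p = 1.94e-06; adjusted p = 0.855 with an estimated correlation). The mean score of the list was 0.73, 1.52 and -0.88 in the WT libraries and 0.49, -0.71 and -1.15 in the Het libraries. Saa4, a constitutive serum amyloid gene, had 835, 1034 and 438 CPM in the WT libraries and 405, 449 and 440 CPM in the Het libraries. The most abundant members were the fibrinogen gene Fgb, with 4484 ± 1399 and 3537 ± 51.1 CPM, and the hemopexin gene Hpx, with 4318 ± 2228 and 2670 ± 812 CPM, and Orm3 had 3.66, 6.31 and 0.566 CPM in the WT libraries and 1.29, 0.046 and 0 CPM in the Het libraries. Single livers moved these differences: the log2 fold change was -0.56 without WT replicate 3 and -0.11 without WT replicate 2 for Fgb, -1.01 and -0.24 for Hpx, and -2.25 without WT replicate 2 for Orm3, against -2.98 with all 6 libraries. For Orm3 no fold change is given without Het replicate 1, since the Het values left lay under the floor that a count of 0 allows. In this list 0 genes passed adjusted over the list alone and 1 had an unadjusted p under 0.05. Without WT replicate 2 the list did not pass (camera, Benjamini-Hochberg adjusted p = 0.178), and without WT replicate 3 Saa4 passed the edgeR test with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.023).

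Interferon response genes had lower values in Het livers in 22 of 28 members, with a median of -0.16 (camera, Benjamini-Hochberg adjusted p = 0.00155; adjusted p = 0.805 with an estimated correlation). The immunoproteasome gene Psmb8 had 24.5 ± 2.14 and 19.4 ± 2.32 CPM and the deubiquitinase gene Usp18 1.35 ± 0.0609 and 0.837 ± 0.283 CPM, while the most abundant members Iigp1 and Bst2 had 411 ± 53.5 and 59.4 ± 10.6 CPM in WT and 402 ± 65.0 and 57.1 ± 9.87 CPM in Het livers. Cell cycle genes had lower values in 18 of 21 members, with a median of -0.30 (camera, Benjamini-Hochberg adjusted p = 7.76e-05; adjusted p = 0.472 with an estimated correlation). Ccnd1, the gene of cyclin D1, had 42.7 ± 3.54 and 26.0 ± 8.0 CPM, the replication licensing gene Mcm2 3.42 ± 1.04 and 1.98 ± 0.527 CPM, and the DNA clamp gene Pcna 23.7 ± 1.27 and 23.5 ± 1.53 CPM. Without Het replicate 1 the log2 fold change of Ccnd1 was -0.94, and without Het replicate 3 it was -0.50. Erythroid markers had lower values in 5 of 6 members (camera, Benjamini-Hochberg adjusted p = 0.0126; adjusted p = 0.718 with an estimated correlation), among them the globin genes Hbb-bs, with 110 ± 36.4 and 74.6 ± 29.9 CPM, Hba-a1, with 72.0 ± 18.9 and 51.2 ± 17.7 CPM, and Hba-a2, with 1.74 ± 0.492 and 1.08 ± 0.270 CPM. Hbb-bs had a log2 fold change of -0.89 without Het replicate 3 and -0.28 without WT replicate 2, Hba-a1 -0.79 and -0.26 without the same libraries, and Hba-a2 -0.89 without Het replicate 3 and -0.47 without WT replicate 1. Globin genes share reads between copies, so the split between Hba-a1 and Hba-a2 is uncertain. The interferon list did not pass without Het replicate 3 (adjusted p = 0.324, camera, Benjamini-Hochberg) and the cell cycle list without WT replicate 3 (adjusted p = 0.207). The erythroid list did not pass without WT replicate 2 (adjusted p = 0.0872, camera, Benjamini-Hochberg), WT replicate 3 (0.0522), Het replicate 1 (0.0882) or Het replicate 2 (0.249). With the acute-phase score of each library as a covariate, added after the data were seen, the interferon (0.41) and erythroid (0.121) lists did not pass camera with Benjamini-Hochberg adjustment.

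Transcripts of cytosolic ribosomal proteins had higher values in Het livers in 56 of 60 members, by a median log2 fold change of 0.08 (camera, Benjamini-Hochberg adjusted p = 9.13e-05; adjusted p = 0.855 with an estimated correlation). Rpl4 had 410 ± 19.9 and 412 ± 8.45 CPM, Rplp0 251 ± 8.62 and 275 ± 7.10 CPM, Rpl35 50.8 ± 2.91 and 56.9 ± 3.93 CPM, and Rps29 113 ± 13.3 and 129 ± 5.56 CPM. Imprinted genes had higher values in 17 of 22 members, with a median of 0.07 (camera, Benjamini-Hochberg adjusted p = 0.0279; adjusted p = 0.472 with an estimated correlation). The amino acid transporter gene Slc38a4 had 1148 ± 121 and 1205 ± 157 CPM, Gnas 415 ± 46.6 and 436 ± 17.9 CPM, Inpp5f 31.0 ± 3.50 and 37.0 ± 1.19 CPM, and the long noncoding RNA gene Meg3 2.02 ± 1.10 and 3.75 ± 1.06 CPM. Meg3 had a log2 fold change of 0.60 without WT replicate 1 and 1.398 without WT replicate 3. The counting strand was not given in the sources used here, so values of imprinted genes with an antisense partner are uncertain. The ribosomal protein list did not pass without WT replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0584) or WT replicate 2 (0.0523), and the imprinted list not without WT replicate 2 (0.0961), Het replicate 2 (0.0876) or Het replicate 3 (0.0676). With the acute-phase covariate neither passed (camera, Benjamini-Hochberg adjusted p = 0.173 and 0.219). In the interferon, cell cycle, erythroid, ribosomal protein and imprinted lists 0 genes passed adjusted over the list alone, and 2, 2, 1, 0 and 2 genes had an unadjusted p under 0.05.

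**Figure D2:**
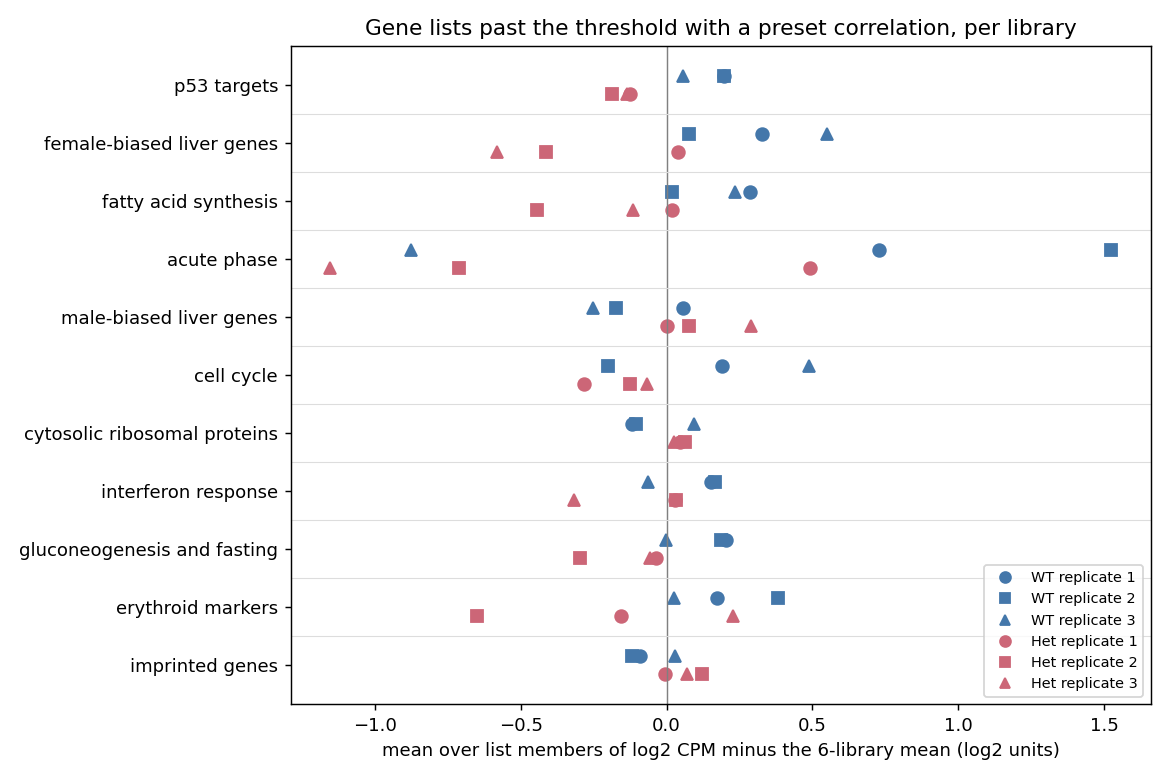
Mean score of each of the 11 gene lists in each library, as the mean over list members of log2 CPM minus the mean of the 6 libraries (horizontal axis, log2 units), with blue points for WT and red points for Het livers. The p53 target scores separate the genotypes at 0.06 to 0.20 in WT and -0.19 to -0.13 in Het livers. So do the female-biased, fatty acid synthesis and gluconeogenesis scores, but by small gaps. Their nearest WT and Het scores are 0.078 and 0.039, 0.0190 and 0.0182, and -0.003 and -0.035, respectively. Each of these lists has an exact permutation p of 0.1, the smallest that 3 against 3 livers allow. Chance gives such a separation in 10% of cases, and 35 lists were tested. The acute-phase scores run from -0.88 to 1.52 within the WT livers.

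The lists closest to the biology of Ing5 did not differ between genotypes past the threshold. The 18 subunits of ING5-containing acetyltransferase complexes had a median log2 fold change of -0.01 (camera, Benjamini-Hochberg adjusted p = 0.619). Their most abundant members were Jade1, with 66.1 ± 1.56 and 71.6 ± 5.30 CPM, and the acetyltransferase gene Ep300, with 40.4 ± 5.64 and 41.2 ± 1.71 CPM. The 31 factors of transgene and heterochromatin silencing, among them Eif3h (90.4 ± 4.27 and 92.5 ± 7.52 CPM) and Baz1b (79.1 ± 5.24 and 75.6 ± 5.21 CPM), gave an adjusted p of 0.688 (camera, Benjamini-Hochberg). The 30 tested genes near Ing5, among them Hdlbp (510 ± 71.2 and 503 ± 47.6 CPM) and Agxt (140 ± 43.2 and 172 ± 24.8 CPM), gave an adjusted p of 0.54 (camera, Benjamini-Hochberg). In these lists 0 genes passed over all genes or adjusted over the list alone, and 1, 0 and 1 genes had an unadjusted p under 0.05. Of the clustered protocadherin genes 1 was expressed highly enough to be tested, and the group summed to 10.03 ± 1.46 CPM in WT and 10.9 ± 1.29 CPM in Het livers.

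The other liver pathways did not pass with all 6 libraries, but several passed when a single liver was left out. The bile acid metabolism list gave an adjusted p of 0.496 (camera, Benjamini-Hochberg), although Cyp7b1 passed adjusted over that list alone (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0158), and its most abundant member Slco1b2 had 2222 ± 263 and 2135 ± 153 CPM. Camera with Benjamini-Hochberg adjustment gave adjusted p-values of 0.0947 for the unfolded protein response, 0.133 for ribosome biogenesis, 0.226 for cholesterol synthesis, 0.307 for xenobiotic metabolism and 0.324 for the circadian clock. It gave 0.496 for immediate early genes, 0.54 for oxidative phosphorylation, 0.585 for sex chromosome genes, 0.626 for heat shock, 0.795 for PPARA targets and fat oxidation, 0.798 for fibrosis and matrix genes and 0.994 for antigen presentation. Without Het replicate 1, the unfolded protein response (1.89e-12), cholesterol synthesis (1.07e-10), PPARA target (0.00336) and ribosome biogenesis (0.00599) lists passed the camera test with Benjamini-Hochberg adjustment and the preset correlation. They did not pass in that fit with the correlation estimated from the libraries (camera, Benjamini-Hochberg; adjusted p = 0.441 to 0.615 with an estimated correlation). Oxidative phosphorylation passed without WT replicate 2 (0.0108) or WT replicate 3 (4.35e-07), and xenobiotic metabolism without WT replicate 2 (5.8e-05), with the preset correlation (camera, Benjamini-Hochberg; adjusted p = 0.993, 0.71 and 0.367 with an estimated correlation). The unfolded protein response (0.0252), ribosome biogenesis (0.0442) and cholesterol synthesis (0.0141) lists passed without WT replicate 1, again only with the preset correlation (camera, Benjamini-Hochberg; adjusted p = 0.846 with an estimated correlation for each). Cholesterol synthesis (0.0136), immediate early (0.00376), fibrosis (0.0314) and antigen presentation (0.0136) lists passed without Het replicate 2, with the same limit (camera, Benjamini-Hochberg; adjusted p = 0.795 with an estimated correlation for cholesterol synthesis and 0.517 for the others). The direction turned for cholesterol synthesis without Het replicate 2 and for oxidative phosphorylation without WT replicate 2. With the acute-phase covariate the xenobiotic metabolism (1.57e-05), oxidative phosphorylation (0.00105) and immediate early (0.0364) lists passed camera with Benjamini-Hochberg adjustment and the preset correlation, but not otherwise (adjusted p = 0.71, 0.918 and 0.71 with an estimated correlation). For the PPARA target, fibrosis and antigen presentation lists the median and mean log2 fold change were positive while the direction of the camera test was down.

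Markers of the cell types of the liver did not differ past the threshold, apart from the erythroid list, which passed camera with Benjamini-Hochberg adjustment only with the preset correlation (adjusted p = 0.0126; adjusted p = 0.718 with an estimated correlation). Camera with Benjamini-Hochberg adjustment gave adjusted p-values of 0.307 for hepatocyte identity, 0.496 for pericentral and 0.994 for periportal hepatocytes, 0.85 for Kupffer cells and macrophages, and 0.133 for stellate cells and fibroblasts. It gave 0.566 for endothelial cells and 0.54 for both cholangiocytes and B or plasma cells. Among the examples, the pericentral cytochrome gene Cyp2e1 had 8101 ± 506 and 8915 ± 453 CPM, the periportal urea cycle gene Cps1 2074 ± 417 and 2345 ± 614 CPM, the Kupffer cell gene Clec4f 61.5 ± 13.9 and 62.6 ± 14.3 CPM, and the stellate cell gene Dcn 96.4 ± 24.5 and 115 ± 20.3 CPM. T and NK cell markers summed to 5.94 ± 1.28 and 6.38 ± 3.72 CPM and neutrophil markers to 3.36 ± 1.09 and 2.72 ± 0.319 CPM, with 3 and 2 members tested. Kupffer cell markers passed without WT replicate 3 (camera, Benjamini-Hochberg adjusted p = 0.046), Het replicate 2 (0.00185) or Het replicate 3 (0.00959), with the direction down in the first pair of fits and up in the last. None of these held when the correlation was estimated (camera, Benjamini-Hochberg; adjusted p = 0.81, 0.755 and 0.85 with an estimated correlation). Stellate cell markers passed without WT replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0442), WT replicate 3 (0.00904) or Het replicate 3 (0.02), with the preset correlation only (adjusted p = 0.846, 0.71 and 0.85 with an estimated correlation). With the acute-phase covariate the endothelial (0.0145), Kupffer cell (0.00711) and periportal (0.0402) lists passed camera with Benjamini-Hochberg adjustment and the preset correlation (adjusted p = 0.828, 0.918 and 0.71 with an estimated correlation). For periportal hepatocytes the median and mean log2 fold change were negative while the direction of the camera test was up.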

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

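The newer quasi-likelihood fit, the acute-phase covariate and the p53 target list without Cdkn1a were chosen after the results were seen. The number of genes changed, Het versus WT, was 0 with edgeR and also with DESeq2 size factors, the stricter filter, library sizes without the 20 most abundant genes, no robust estimation, a threshold of 0.1, the newer fit, the covariate and limma-voom (547 genes had an unadjusted p under 0.05 in edgeR and 571 in limma-voom). It was 1 with no low-count filter (Gnat1), 14 with DESeq2, and 0 to 17 with 1 library left out; the cause was not tested. The number of gene lists changed was 11 and became 0 with the estimated correlation and 0 with fry, which allow for genes that vary together, and it was 9 to 14 with 1 library left out (0 with the estimated correlation in each such fit, smallest adjusted p 0.107). The drop to 0 cannot be put down to such genes alone. For a simulated list of independent genes the adjusted p also rose, from 1.02e-19 with the preset to 0.0177 with the estimated correlation (camera). The Ing5 log2 fold change was -0.116 to 0.00771 with 1 library left out and negative under each other alternative run. The labels state no pairing by replicate number. Same-number deviations correlated at -0.0247, -0.078 and 0.224, which are too few values to decide whether such livers were paired. With the replicate block 0 genes passed, with a smallest adjusted p of 0.0878 against 0.529 without it (edgeR, Benjamini-Hochberg). In the block fit 11 lists passed with the preset but 0 with the estimated correlation (smallest adjusted p 0.398, camera).

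Besides Ing5, the fold changes of 51 genes were followed over the alternatives, and those of the other genes named here were not. Of the 51, these turned sign with 1 library left out: Slc38a4 (-0.00732 to 0.171), Fads1 (-0.068 to 0.101), Tat (-0.532 to 0.101), Serpina3k (-0.0235 to 0.221), Iigp1 (-0.133 to 0.0952), Bst2 (-0.182 to 0.075), Pcna (-0.0543 to 0.0431), Perp (-0.261 to 0.00248) and Rpl4 (-0.0248 to 0.0462). With the covariate, Slc38a4 (-0.0766), Gnas (-0.011), Iigp1 (0.118) and Rpl4 (-0.0139) turned sign, as did the lists OXPHOS (adjusted p 0.00105) and periportal_hepatocyte (0.0402), of which neither passed with the estimated correlation (0.918 and 0.71). The direction turned for cholesterol_synthesis without Het replicate 2 (adjusted p 0.0136; 1.07e-10 to 0.775 over all fits with 1 library left out), OXPHOS without WT replicate 2 (0.0108; 4.35e-07 to 0.982) and Kupffer_macrophage without WT replicate 3 or Het replicate 2 (0.046 and 0.00185; 0.00185 to 0.715). These used the preset correlation, and with the estimated one the turned fits gave 0.795, 0.993, 0.81 and 0.755. The cause of these turns was not tested.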

Other observations

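The tests of the 10 splits of the libraries for edgeR genes and for lists, of the acute-phase covariate, of the p53 target list without Cdkn1a, and of exchanged labels were chosen after the results they concern were seen, and the estimated correlation, fixed beforehand as a setting, was taken as a test of genes varying together only then.

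Individual livers differed in whole groups of genes within a genotype. The acute-phase genes Saa1, Saa2, Orm2 and Lcn2 were high in WT replicates 1 and 2 and in Het replicate 1: Saa1 had 1382, 4302 and 31.3 CPM in WT replicates 1 to 3 and 754, 44.9 and 24.0 CPM in Het replicates 1 to 3. Lcn2 had 64.7, 323 and 2.37 CPM in the WT and 92.5, 1.89 and 0.927 CPM in the Het libraries. Cholesterol synthesis and fat oxidation genes were high in Het replicate 1, with Sqle, the squalene epoxidase gene, at 67.4 CPM there against 6.86 and 15.8 CPM in the other Het libraries and 23.0, 63.3 and 30.1 CPM in the WT libraries. The PPARA target Cyp4a14 had 629.8 CPM in Het replicate 1 against 38.3 and 54.2 CPM in the other Het libraries and 3.66 to 64.3 CPM in the WT libraries. Kupffer cell scores were -0.54 in WT replicate 3 and -0.39 in Het replicate 3 against 0.26 and 0.24 in WT replicates 1 and 2 and -0.05 and 0.48 in Het replicates 1 and 2. Reads of the Saa, Orm and Cyp4a families can be shared between copies, so the split between their members is uncertain.

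Without WT replicate 3, 17 genes passed the edgeR test, 14 of them lower in Het livers, including Stat3 (log2 fold change -0.72), Il6ra (-0.58), Il1r1 (-0.88), Il13ra1 (-0.63), Nnmt (-2.90) and Saa4 (-1.12). The WT livers left in that fit were those with acute-phase scores of 0.73 and 1.52, against -0.88 in WT replicate 3. Without Het replicate 1, 10 genes passed, including the major urinary protein gene Mup18 (2.24), Cyp2b9 (-2.20), Cyp2c38 (-1.03), Cyp2c39 (-1.52) and Ugt2b38 (1.54). Mup18 had 7.51, 8.76 and 7.71 CPM in the WT libraries and 7.03, 39.9 and 35.5 CPM in the Het libraries. Reads of the Mup and Cyp2c families can likewise be shared between copies, so the values of their members are uncertain. These 2 sets shared 0 genes, and each shared 2 genes with the 14 of DESeq2.

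The first pattern is the 11 lists past the threshold with a preset correlation, led by the p53 targets. With the correlation estimated from the libraries 0 of the 11 lists passed. Estimates were high for some lists (0.702 for acute phase, 0.667 for cytosolic ribosomal proteins) but near the preset 0.01 for others (0.0147 for imprinted genes). The p53 targets were lost even at -0.0157, without WT replicate 3 (adjusted p = 0.318, camera, Benjamini-Hochberg). Losing a call thus cannot show that genes of a list vary together between livers. Of the 10 splits of the libraries, 5 gave at least 11 lists (16 in the highest other split). Here 10 splits are too few for a share under 0.05. For the p53 targets 1 of 10 splits, the split by genotype, gave a camera p as small as 6.9e-11 (0.00198 in the strongest other split), with the same limit. The p53 list had the smallest camera p of the 35 lists in the split by genotype, so comparing splits for this list leans towards that split. Another split gave a smaller camera p than genotype for the female-biased (4.71e-09 against 6.34e-09), male-biased (1.12e-08 against 5.63e-06) and acute-phase (5.68e-38 against 2.22e-07) lists. Lower values were not limited to Cdkn1a, since 19 of 22 p53 targets had them. With the preset correlation the p53 list had an adjusted p of 2.87e-07 without Cdkn1a and 5.53e-06 with the acute-phase score as a covariate (camera, Benjamini-Hochberg). Settings changed singly gave it 2.5e-09 to 0.207, and the covariate with the estimated correlation gave 0.245 (camera, Benjamini-Hochberg). The preset correlation also passed lists in splits not by genotype, so these p-values cannot exclude Cdkn1a or the acute-phase state as a main source. A lower level of p53 targets in Het livers is thus a hypothesis that did not pass with the estimated correlation (adjusted p = 0.207, camera, Benjamini-Hochberg). The lost call does not decide whether variation shared between livers is a source.

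The second pattern is the 14 genes that passed with DESeq2, where edgeR gave 0 and limma-voom 0. They were Gnat1, Tsku, Cyp21a2-ps and Hjurp with lower and Ugt2b38, Abca8a, Cyp7b1, Dnaic1, Hsd3b5, Hsd3b2, Slco2a1, Avpr1a, Gm16551 and Lifr with higher values in Het livers. With DESeq2, 6 of the 10 splits gave at least 14 genes (209 in the highest other split), where 10 splits are too few for a share under 0.05, while with edgeR the 0 genes of the split by genotype (1 in the highest other) fixed that count at 10 of 10, which tests nothing. A candidate explanation for Hjurp is a variant carried along with the Ing5 allele, since Hjurp lies on the same stretch of chromosome 1. It is 37 places from Ing5 in the order of tested genes. Ugt1a2, Col6a3, Bok and Sag, which had an unadjusted p under 0.05 in edgeR, are 40, 31, 4 and 49 places away. Of the 100 tested genes nearest to Ing5 5 (5%) had such a p against 532 of 12235 others (4.35%), a one-sided Fisher's exact p of 0.442, so too few genes decide it and the origin of Hjurp's difference stays open.

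The third pattern is the difference in acute-phase genes between libraries of the same genotype. The acute-phase score differed by -0.92 (log2) between the group means. An exchange of the labels of WT replicate 3 and Het replicate 1 was considered. The split with these exchanged gave 1502 genes with an unadjusted p under 0.05 (edgeR), against 547 in the split by genotype and 993 in the next. It gave 209 genes in DESeq2 and 6 in limma-voom (for limma-voom 0 in the split by genotype, at most 1 in any other). However, this split sets the livers with the highest acute-phase scores (0.73, 1.52 and 0.49) against those with the lowest (-0.88, -0.71 and -1.15). It thus sorts the libraries by the pattern to be explained, so its larger counts cannot speak for an exchange. The exchanged split gave 0 genes past the adjusted threshold with edgeR. An exchange and a difference in inflammatory state between livers cannot be told apart here, because nothing in the gene counts marks the genotype: the Ing5 counts did not differ past the threshold. The reads were not searched for the mutation. No biological explanation was tested for it.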
